A study of Mus musculus with 4 samples.

How the data were processed

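The series holds 4 Visium libraries from coronal sections of the mouse head at embryonic day 14, cut at 10 µm from fresh-frozen tissue. Visium captures polyadenylated RNA on an array of barcoded spots and counts unique molecular identifiers (UMIs), so that each spot reads a small piece of tissue that can hold several cells. The labels give 2 libraries as Control (Foxc1 wild type) and 2 as Foxc1 mutant (Foxc1 knockout). They do not say whether the sections came from separate embryos, where along the head they were cut, or which part of Foxc1 was deleted. P-values therefore measure the spread between these sections, part of which may be technical.

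The deposited matrices hold raw UMI counts per gene and spot, made by the authors with Space Ranger on genome build mm10, per the submitters' processing notes, which also name Seurat and give no versions. The deposited counts had not been normalized: they were whole numbers whose totals differed between sections. The gene tables listed 32285 genes, of which 38 symbols named several identifiers and were kept apart by identifier. The deposited spot positions were used to draw maps and to find neighbouring spots. The image scale factors were not used here. Gene positions came from the RefSeq annotation of GRCm38.p6, whose symbols matched 26296 of the 32245 symbols in the files. The aligner settings and the gene annotation release are not given in the sources used here.

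Spots over tissue with at least 500 UMIs were kept. This left 1318 of 1321 spots in Control 1, 1614 of 1620 in Control 2, 2147 of 2155 in Foxc1 mutant 1 and 1521 of 1523 in Foxc1 mutant 2. Counts were scaled to 10000 per spot and log-transformed, 2000 variable genes were chosen with section as batch, and 30 principal components and 15 neighbours were used for Leiden clustering at resolution 1.0 (scanpy 1.11.5, with the Leiden implementation of igraph 0.11.9). The 272 members of the fixed gene lists were left out of the clustering genes, as were the mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes and genes seen in fewer than 10 spots. Each of the 25 clusters was given to a region by marker genes fixed before the data were examined. A cluster stayed unnamed if markers of another region outnumbered its own among its 10 leading genes. No doublet caller was run, because a spot holds several cells by design. No deconvolution was run.

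UMI counts were then summed per section over the spots of a region, giving 1 library per section and region, because spots of a section are not replicates. Summed cortex libraries held 2164565, 4990316, 3415813 and 2319169 UMIs in Control 1, Control 2, Foxc1 mutant 1 and Foxc1 mutant 2. The corresponding mesenchyme libraries held 3208904, 3566916, 3831556 and 3259766 UMIs, and the ventral telencephalon libraries 864165, 1964398, 4771213 and 4049639. The shallow ventral library of Control 1 limits the precision of that comparison. Libraries were compared with edgeR 4.0.16 (TMM normalization, filterByExpr by group, glmQLFit and glmQLFTest, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Counts at an unadjusted p under 0.05 are also given. With no true change, a share of 0.05 of the tested genes would reach that level. All log2 fold changes are the libraries labelled mutant over the Control libraries. Those of single genes carry the standard error of the fit, with 2 sections per group. Standard errors of list medians come from the spread over list members and do not measure the spread between sections. An exact permutation test of 2 sections against 2 cannot give a two-sided p below 0.333, so single values such as shares of spots were not tested.

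The 21 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with the correlation estimated per list, and with fry. Camera compares the members of a list with all other genes. The difference of the mutant effect between cortex and ventral telencephalon was tested as an interaction in 8 summed libraries with section as a block. Genes were named by a rule fixed beforehand. It took Foxc1 first and then, per region, the 8 largest changes in each direction past the threshold, with non-overlapping sections and a mean of at least 10 CPM in the higher group. Xist, Y-linked, mitochondrial and unnamed predicted genes stayed in the counts but were not named. Where fewer than 3 passed in a direction, the 5 smallest p-values were named. In the cortex and mesenchyme it added members of each list past the threshold or the smallest p-values of the list, and in the cortex 11 genes by name. Members of lists with no call in the mesenchyme are given as counts, except for meningeal fibroblasts and for genes whose sign turned with the setting. Some genes that the rule names are not reported here.

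Each fit was tested on simulated counts with the real means, depths and dispersions and 200 genes changed. The cortex fit recovered 56% of 2-fold and 98% of 4-fold changes among 11971 genes. The mesenchyme fit recovered 89% and 100% among 12840 genes, the ventral telencephalon fit 49% and 98% among 12395, the whole-section fit 96% and 100% among 15729, and the interaction 44% and 94% among 12709. These rates hold for simulated data with 200 changed genes. The real whole-section fit left log2 fold changes of -2.43 (Slc22a6, adjusted p = 0.232), -4.22 (Mmp13, 0.102) and 5.18 (Gbx1, 0.102) uncalled. A lack of calls therefore does not show that such changes were absent. In a simulated cortex where only the cell cycle list was shifted, by 0.5 on the log2 scale, camera gave that list an adjusted p of 3.41e-14 at the preset correlation and 0.255 with an estimated correlation. Simulated genes vary independently, while the correlation estimated in the cortex was 0.912 for cell cycle, 0.897 for mitochondrial and 0.892 for erythroid genes. The simulation therefore does not test for false list calls at the preset correlation. With an estimated correlation the simulated shift was missed, so a call lost that way does not show that a list was unshifted. Nor does it show that correlated genes made the call. Among lists called in the cortex, the estimate was below the preset value for retinoic acid synthesis and transport (-0.128), mural cells, Cajal-Retzius cells and BMP targets. It was above that value for the other called lists.

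Alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, leaving out each section, the replicate number as a block, thinning to the smallest library, leaving out haemoglobin, mitochondrial and ribosomal protein genes, at least 1000 UMIs per spot, clusters at resolution 2.0 (38 clusters), assignment of spots by marker score, and interior spots whose neighbours all shared their region. A neighbouring position without a kept spot did not count against a spot, so spots at the tissue edge could be interior. Comparisons of single clusters, and a cortex without the cluster that mixed dorsal and ventral telencephalic markers, were added after the data had been seen. That mixed cluster was picked as the cortex cluster with Gm42418 among its leading genes. No pair of sections agreed closely enough to be a repeat of one library: correlations of log2 CPM over whole sections lay between 0.98 and 0.989.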

Results

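Spatial transcriptomes were collected from 4 coronal head sections of embryonic day 14 mice, 2 labelled Control and 2 labelled Foxc1 mutant. Foxc1 encodes a forkhead transcription factor made by the mesenchyme that forms the meninges, and the title of the series concerns retinoic acid from the meninges, Notch, Sox2 and neurogenesis. Totals were 14875112 UMIs in Control 1, 21448510 in Control 2, 25098285 in Foxc1 mutant 1 and 21912558 in Foxc1 mutant 2. The median spot held 10731 UMIs in Control 1, 12070 in Control 2, 10816 in Foxc1 mutant 1 and 13485 in Foxc1 mutant 2. Control 1 stood apart in its share of mitochondrial UMIs, 6.1% against 4.06% in Control 2, 3.58% in Foxc1 mutant 1 and 3.66% in Foxc1 mutant 2. Haemoglobin transcripts took 1.57% ± 0.54 of UMIs in the Control sections and 2.92% ± 0.25 in the sections labelled mutant (SD, n = 2 each).

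The targeted gene was examined first, and its counts were higher in the libraries labelled as its knockout. Foxc1 (ENSMUSG00000050295; GRCm38 chromosome 13, 31806646 to 31810635) gave 1829 UMIs in Control 1 and 1070 in Control 2, against 4439 in the library labelled Foxc1 mutant 1 and 4461 in the library labelled Foxc1 mutant 2. In whole sections this was 122 and 49.9 CPM in the Control libraries and 179 and 204 CPM in the libraries labelled mutant. The transcript was most abundant in the meningeal cluster, whose leading genes included Foxc1, Foxd1, Foxc2 and Cldn11. There it reached 316 ± 132 CPM in Control and 837 ± 53 CPM in the libraries labelled mutant (SD, n = 2 each), a log2 fold change of 1.41 ± 0.22 (SE; edgeR adjusted p = 0.0463). The increase also passed the threshold in the mesenchyme, at 1.45 ± 0.22 (adjusted p = 0.0478), and in the ventricular cluster of the cortex, from 54 ± 37 to 188 ± 59 CPM (2.03 ± 0.33, adjusted p = 0.00563; 26 and 20 UMIs in the Control libraries). It did not pass in the cortex (1.13 ± 0.38, adjusted p = 0.402), the ventral telencephalon (1.03 ± 0.38, adjusted p = 0.561) or the whole section (1.16 ± 0.37, adjusted p = 0.807). DESeq2 called Foxc1 in none of these 3 sums, and in the mesenchyme RLE normalization (adjusted p = 0.0599) and finer clusters (0.515) ended the call. A tag outside the deleted part of a gene checks nothing about the genotype, and the labels do not give the position of the deletion. The libraries are therefore named by their labels throughout, and every direction below rests on those labels.

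**Figure D1:**
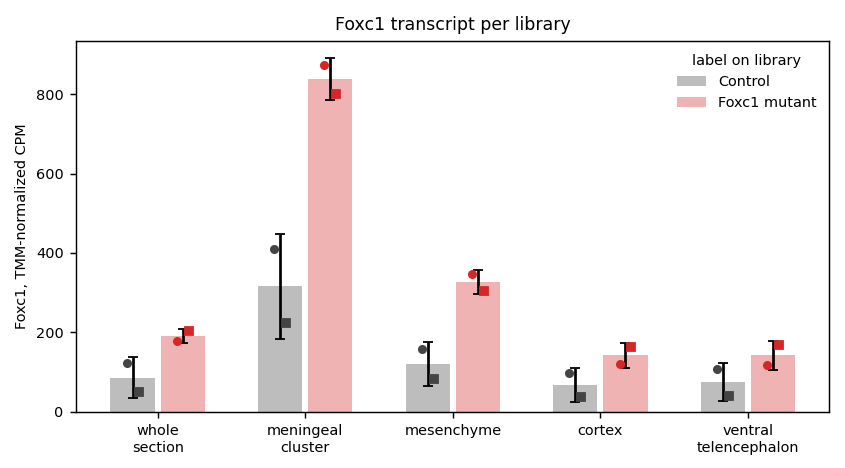
Foxc1 in TMM-normalized CPM (y axis) in sums of spots over 5 parts of the sections (x axis), with Control libraries in grey and libraries labelled Foxc1 mutant in red. Bars are means of 2 libraries, error bars are SD, circles are replicate 1 and squares replicate 2. In the meningeal cluster the Control libraries lie at 409 and 222 CPM and the libraries labelled mutant at 875 and 800 CPM.

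The makeup of the sections differed between the labels. Cortex clusters covered 20.8% ± 0.47 of spots in the Control sections and 12.7% ± 3.1 in the sections labelled mutant, while ventral telencephalon clusters covered 4.95% ± 1.4 and 16% ± 4.5 (SD, n = 2 each). Mesenchyme covered 17.5% ± 1.3 and 14.5% ± 0.43, and the meningeal cluster 3.67% ± 0.72 and 3.99% ± 0.12. Of the cortex spots, 25.4% in Control 1 and 9.67% in Control 2 lay within 2 spots of the meningeal cluster, against 5.94% in Foxc1 mutant 1 and 1.26% in Foxc1 mutant 2. The ventricular cluster, led by Fabp7, Lhx2 and Neurog2 and so by genes of cortical progenitors, made up 15.4% and 24.5% of cortex spots in Control 1 and Control 2 and 45.9% and 51.6% in Foxc1 mutant 1 and Foxc1 mutant 2. This contrast rested in part on the denominator: of all spots the cluster held 3.26%, 5.02%, 6.85% and 5.39% in the same order. Both sections labelled mutant still lay above both Control sections, the nearest values being 5.02% and 5.39%. A cortex cluster that also carried ventral telencephalic markers held 228 of the 279 cortex spots of Control 1, but 115 of 331 in Control 2, 71 of 320 in Foxc1 mutant 1 and 32 of 159 in Foxc1 mutant 2. Its 10 leading genes included Gm42418 and Lars2 and no fixed marker of the ventral telencephalon. The median spot of this cluster held 7424.5 UMIs, against 8078 in the ventricular cluster and 20711 and 20062 in the remaining cortex clusters. Whether RNA quality shaped it was not tested. Without this mixed cluster the ventricular cluster was 43 of 51 cortex spots in Control 1, 81 of 216 in Control 2, 147 of 249 in Foxc1 mutant 1 and 82 of 127 in Foxc1 mutant 2, so that Control 1 had the highest share. A ventral cluster led by Nkx2-1, a gene of the medial ganglionic eminence, held 137 spots of Foxc1 mutant 2, 4 of Foxc1 mutant 1 and none of the Control sections, so the sections did not show the same ventral territory. No share was tested, since 2 sections against 2 cannot give a two-sided exact p below 0.333. With finer clusters the cortex covered 15.2% ± 3.9 (Control) and 12% ± 1.9 (labelled mutant) and the ventral telencephalon 9.36% ± 4.5 and 15.7% ± 3.6. With marker scores these were 14.7% ± 5 and 11.3% ± 3.2, and 8.04% ± 2.3 and 14.5% ± 2.8. Under both the cortex shares of the labels overlapped, with Control 1 (12.5% and 11.1%) below Foxc1 mutant 1 (13.3% and 13.6%).

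**Figure D2:**
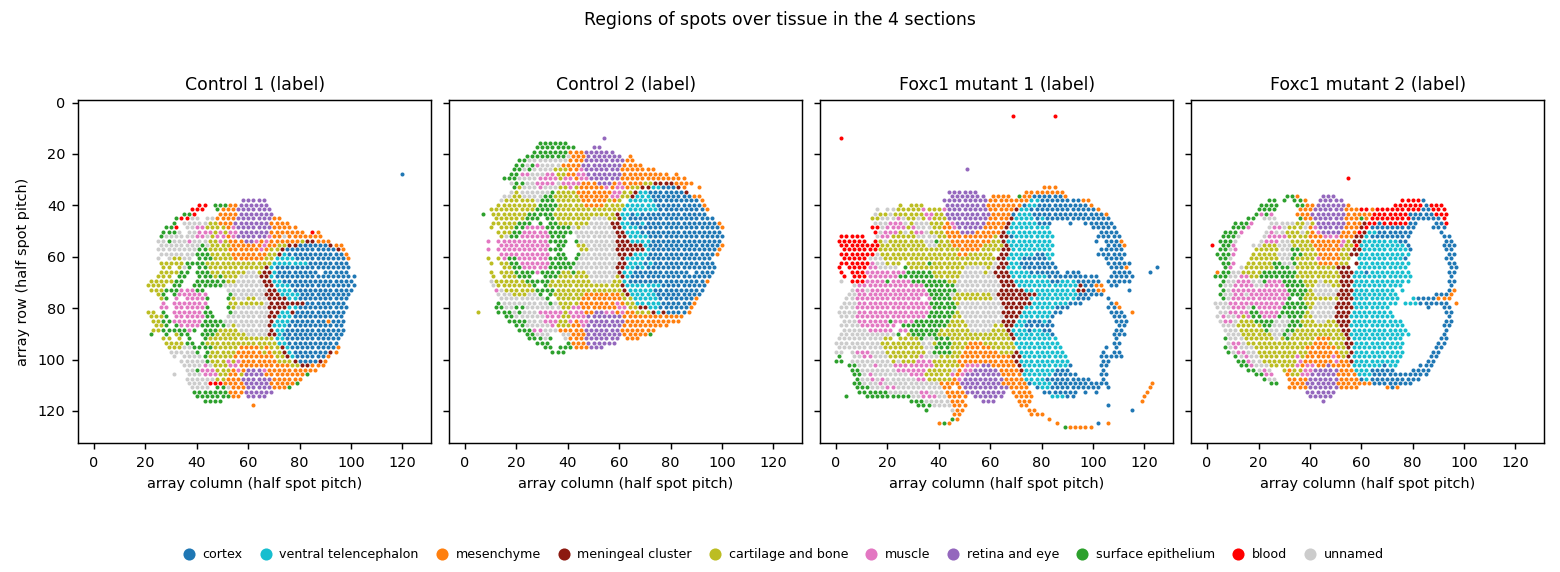
Position of every kept spot on the array of each of the 4 sections (x axis, array column, and y axis, array row, both as positions on the array), coloured by region. The meningeal cluster is drawn apart from the remaining mesenchyme. The cortex holds 279 spots in Control 1, 331 in Control 2, 320 in Foxc1 mutant 1 and 159 in Foxc1 mutant 2.

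The cortex was compared because the study concerns neurogenesis there. Of 11971 genes, 14 passed the threshold, 12 lower and 2 higher in the libraries labelled mutant (edgeR). The 12 lower genes included 5 collagen genes. Col1a1 (ENSMUSG00000001506; GRCm38 chromosome 11, 94936224 to 94953042), which encodes a main collagen of connective tissue, fell from 1252 ± 67 to 317 ± 41 CPM (SD, n = 2 each; log2 fold change -1.98 ± 0.21 SE, adjusted p = 0.0239), and Col1a2 from 1087 ± 115 to 349 ± 4.1 CPM (-1.64 ± 0.2, adjusted p = 0.0286). Slc22a6 (ENSMUSG00000024650; chromosome 19, 8617996 to 8628299), an organic anion transporter gene, fell from 14.7 ± 0.025 to 0.661 ± 0.32 CPM (-4.32 ± 0.53, adjusted p = 0.0286), with 3 and 1 UMIs in the libraries labelled mutant. Cldn11, a tight junction gene, fell by 3.35 on the log2 scale (SE 0.5, adjusted p = 0.0464), and the forkhead gene Foxd1 by 3.13 (SE 0.47, adjusted p = 0.0464). Col8a2, Thbs2, Col14a1 and Islr fell by 3.08, 2.59, 2.33 and 2.14, with adjusted p between 0.0239 and 0.0454. Col5a2 and Pcolce, which were also lower and called, lay outside the naming rule and were named after their values were seen. The higher genes were the long noncoding RNA AW047730 (14.9 ± 6.8 to 73.3 ± 0.85 CPM, 2.21 ± 0.28, adjusted p = 0.0325) and Aldoc, a glycolytic aldolase of radial glia (53.4 ± 8.3 to 153 ± 25 CPM, 1.51 ± 0.22, adjusted p = 0.0454). Aldoc was among the 10 leading genes of the ventricular cluster. Next by p-value among the higher genes, and not past the threshold, were Esm1 (adjusted p = 0.0534), Car14 (0.0698) and Nr2f1 (0.0948).

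No gene passed with finer clusters, over interior spots or without the mixed cluster. Marker scores gave 10 genes, 6 of them among the 14, and a minimum of 1000 UMIs per spot gave the same 14. Thinning the libraries to the smallest also left 0, while DESeq2 called 65 genes and 960 had an unadjusted p under 0.05 by edgeR. The number of genes changed in the cortex was 366 without Control 1, 1964 without Control 2, 139 without Foxc1 mutant 1 and 68 without Foxc1 mutant 2.

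The lists of fibroblast and vascular genes shifted down in the cortex. Of 17 measured meningeal fibroblast genes 16 were lower, with a median log2 fold change of -1.18 (camera adjusted p = 1.76e-28, and 0.236 with an estimated correlation). 3 of them passed over all genes, Col1a1, Col1a2 and Foxd1, and 12 passed when adjusted over the list alone, including Foxc1, which was higher. Genes of retinoic acid synthesis and transport were not shifted over whole sections (4 higher and 6 lower, median -0.09, camera adjusted p = 0.924). In the cortex all 7 measured genes of this list were lower (median -1.21, adjusted p = 4.03e-09, and 0.236 with an estimated correlation). Of the 7, 6 were past the threshold when adjusted over the list alone and none over all genes. Among these, Aldh1a2, which makes retinoic acid in the meninges, had 21.8 ± 10 CPM in Control and 4.56 ± 2.8 in the libraries labelled mutant (-2.12 ± 0.48, adjusted p over all genes 0.159), the retinol receptor gene Stra6 a log2 fold change of -1.37 ± 0.34 (0.202) and the retinol dehydrogenase gene Rdh10 -1.2 ± 0.31 (0.226). Genes of basement membrane (10 of 12 lower, median -0.48), mural cells (7 of 8, -0.47), endothelium (10 of 14, -0.31), macrophages and microglia (9 of 10, -0.41), BMP targets (6 of 8, -0.32) and Cajal-Retzius cells (5 of 6, -0.5) were called down as well, with adjusted p between 3.97e-07 and 0.00515. With an estimated correlation none of these lists was called, with adjusted p between 0.236 and 0.362. The estimate was below the preset 0.01 for mural cells (-0.11), Cajal-Retzius cells (-0.132) and BMP targets (-0.097). It was above 0.01 for basement membrane (0.165), endothelium (0.146) and macrophages and microglia (0.0556). Reln, the signalling protein gene of Cajal-Retzius cells, had a log2 fold change of -1.02 ± 0.2 (adjusted p = 0.105), the basement membrane gene Nid2 -1.33 ± 0.21 (0.0534) and the endothelial tight junction gene Cldn5 -1.14 ± 0.27 (0.174). Fry called meningeal fibroblasts, mural cells, Cajal-Retzius cells and BMP targets, each at adjusted p = 0.0476. Without Control 2 camera did not call endothelium (adjusted p = 0.372), mural cells (0.0641), BMP targets (0.0709) or macrophages and microglia (0.152), and without Foxc1 mutant 2 it did not call endothelium (0.112). Without the mixed cluster it did not call endothelium (0.112), mural cells (0.202) or Cajal-Retzius cells (0.19), and over interior spots it did not call endothelium (0.171).

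Transcripts of some tissues outside the brain were lower in the same cortex spots. All 12 measured markers of cartilage and bone were lower (median log2 fold change -1.64), as were all 9 of muscle (-2.23) and all 6 of the eye (-1.4), while over whole sections these medians were -0.5, 0.09 and -0.15. Markers of surface epithelium were lower in 7 of 9 cases (-0.69), and those of blood higher in 7 of 7 (0.52). In the ventral telencephalon the medians were -1.65, -1.5 and -1.02. Markers of the ventral telencephalon were lower in the cortex in 13 of 13 cases (median -0.7). In cortex spots the medians of cartilage and bone, muscle and eye markers lay below that of retinoic acid synthesis and transport (-1.21). Whether these falls share a source was not tested.

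**Figure D3:**
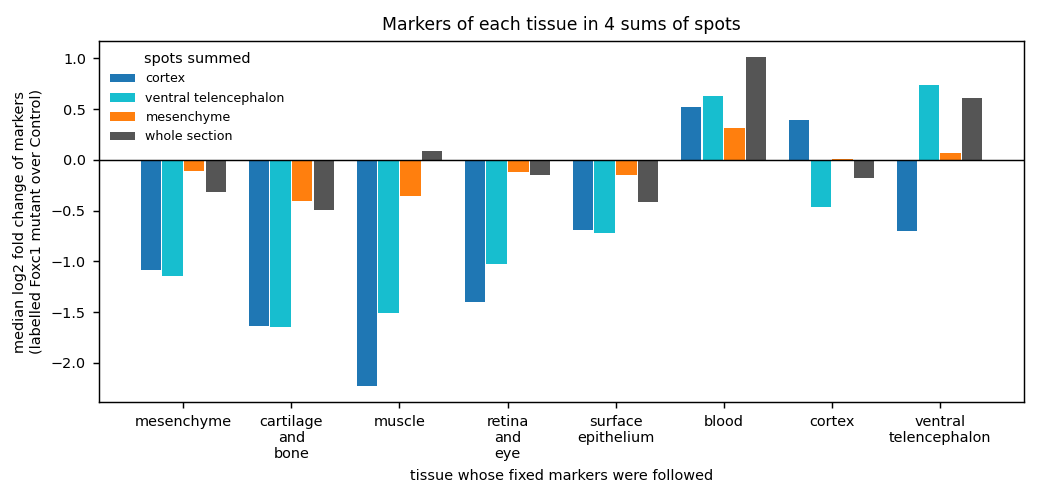
Median log2 fold change (y axis, libraries labelled Foxc1 mutant over Control) of the fixed markers of 8 tissues (x axis) in the summed spots of the cortex, the ventral telencephalon, the mesenchyme and the whole section (bar colours). In cortex spots the muscle markers have a median of -2.23, against 0.09 in the whole section.

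Among genes named by the title of the series, retinoic acid receptors and responsive genes were called down in the cortex (7 of 8 lower, median -0.47, adjusted p = 0.00976, and 0.421 with an estimated correlation). Rarb, a receptor gene that retinoic acid induces, had 12.5 ± 6.5 CPM in Control and 2.95 ± 2.9 in the libraries labelled mutant (-1.88 ± 0.63, adjusted p = 0.402), and Cyp26b1, whose enzyme degrades retinoic acid, had a log2 fold change of -0.4 ± 0.41 (0.857). All 6 measured Notch targets were higher (median 0.33, adjusted p = 0.0129, and 0.49 with an estimated correlation), none past the threshold singly. Hey1 had a log2 fold change of 0.79 ± 0.28 (adjusted p = 0.43), Hes5 0.62 ± 0.27 (0.598) and Hes1 0.2 ± 0.28 (0.897). The list of Notch receptors, ligands and modulators was called up with 10 of 18 genes higher (median 0.09, adjusted p = 0.0474, and 0.362 with an estimated correlation). The fringe genes Lfng and Mfng and the ligand gene Dll1 passed when adjusted over the list alone. Notch1 was at 85.9 ± 22 and 95.2 ± 8 CPM (0.16 ± 0.23, adjusted p = 0.9), and Sox2, the progenitor transcription factor gene, at 112 ± 51 and 121 ± 14 CPM (0.13 ± 0.29, adjusted p = 0.94). Without Control 2 the log2 fold changes of Sox2, Notch1 and Hes1 were -0.28, -0.08 and -0.13, while without Control 1 Sox2 was called up (0.68, adjusted p = 0.0132). Without Control 2 and without Foxc1 mutant 2 the calls of the Notch targets (adjusted p = 0.46 and 0.332) and of the Notch receptors, ligands and modulators (0.544 and 0.236) were lost, and that of the retinoic acid receptors was lost without Control 1 (0.118) and without Foxc1 mutant 2 (0.0516). Marker scores ended the calls of the retinoic acid receptors (0.059) and of the Notch receptors, ligands and modulators (median -0.09, 0.159).

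Progenitor lists were higher in the cortex of the libraries labelled mutant. With the mixed cluster included, the ventricular cluster also made up more of the cortex spots there (45.9% and 51.6%, against 15.4% and 24.5% in Control). Makeup of the spots and expression within cells therefore cannot be told apart. All 11 genes of intermediate progenitors, the neuron-producing daughters of radial glia, were higher (median 0.5, adjusted p = 3.53e-06, and 0.236 with an estimated correlation), and 4 passed when adjusted over the list alone. Eomes, which marks these cells, had 58.9 ± 3.8 CPM in Control and 123 ± 36 in the libraries labelled mutant (1.05 ± 0.24, adjusted p over all genes 0.17), and Gadd45g had a log2 fold change of 0.78 ± 0.23 (0.31). Of 28 cell cycle genes 23 were higher (median 0.36, adjusted p = 2.84e-05, and 0.528 with an estimated correlation), none past the threshold singly, with Mcm5 at 0.83 ± 0.26 (adjusted p = 0.374) and Aurka at 0.82 ± 0.26 (0.377). Radial glia genes were called up with 12 of 18 higher (median 0.08, adjusted p = 0.0278, and 0.611 with an estimated correlation), and Lhx2, Fgfr3, Prom1 and Sox3 passed when adjusted over the list alone. Pan-neuronal genes were called down, with 12 of 16 lower (median -0.26, adjusted p = 0.0295, and 0.49 with an estimated correlation). Genes of excitatory cortical neurons were not called (median 0.09, mean -0.04, adjusted p = 0.981): Tbr1 had a log2 fold change of 0.13 ± 0.34 (0.948) and Neurod6 -0.04 ± 0.23 (0.982). Without Control 2 the calls of radial glia (median -0.16, adjusted p = 0.55), cell cycle (0.878) and pan-neuronal genes (0.101) were lost, as they were without Foxc1 mutant 2 (0.26, 0.0564 and 0.681). Excitatory neurons were called down without Control 1 (median -0.24, adjusted p = 0.000452; Tbr1 -0.36, 0.246) and up without Control 2 (median 0.4, adjusted p = 0.00364; Tbr1 0.93, 1.27e-05). Marker scores or the cortex without the mixed cluster ended the radial glia call (0.681 and 0.304) and the pan-neuronal call (0.359 and 0.331).

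**Figure D4:**
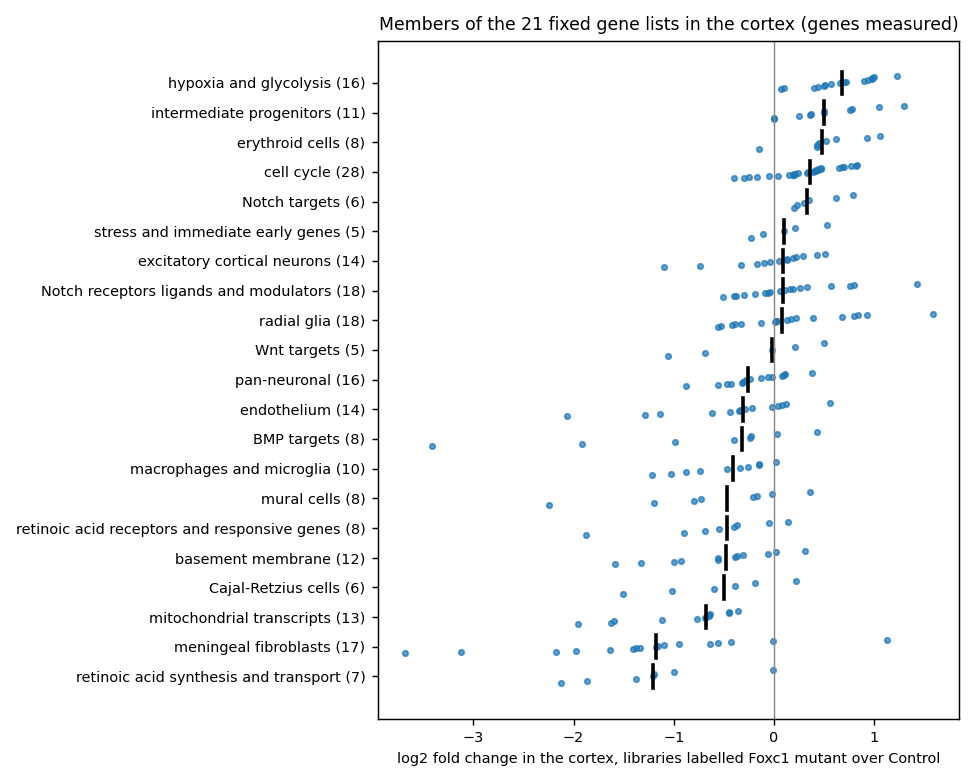
Log2 fold change in the cortex (x axis, libraries labelled Foxc1 mutant over Control) of each measured member (points) of the 21 fixed gene lists (y axis, with the number of genes measured), with the list median as a black bar. The 16 hypoxia and glycolysis genes all lie above 0, and the 7 genes of retinoic acid synthesis and transport all lie below 0.

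Genes of hypoxia and glycolysis were higher in the cortex in 16 of 16 cases (median 0.68, adjusted p = 3.6e-11, and 0.314 with an estimated correlation), and 5 passed when adjusted over the list alone. The glycolytic kinase gene Pgk1 had 300.3 ± 14 CPM in Control and 591 ± 102 in the libraries labelled mutant (0.98 ± 0.2, adjusted p over all genes 0.133), Ldha 465 ± 84 and 915 ± 200 CPM, and the hypoxia-induced gene Bnip3 36 ± 8.6 and 86.5 ± 31 CPM (1.23 ± 0.28, adjusted p = 0.172). Mitochondrial transcripts were lower in 13 of 13 cases (median -0.68, adjusted p = 2.82e-09, and 0.362 with an estimated correlation), and Control 1 had the highest mitochondrial share of the 4 sections. Erythroid genes were higher in 7 of 8 cases (median 0.48, adjusted p = 0.00515, and 0.49 with an estimated correlation). The lists of stress and immediate early genes (adjusted p = 0.659) and of Wnt targets (0.82) were not called. The erythroid call was lost without Control 2 (0.711), without Foxc1 mutant 2 (0.831), over interior spots (0.171) and with marker scores (0.379). Without Control 2 the number of lists called fell from 18 to 9, and without Foxc1 mutant 2 to 10.

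In the mesenchyme, where Foxc1 is made, 5 of 12840 genes passed the threshold (edgeR). Foxc1 was higher, as given above. Slc22a6 fell from 24.4 ± 6.7 to 6.83 ± 1.4 CPM (log2 fold change -1.82 ± 0.27, adjusted p = 0.0478), and Matn1, a cartilage matrix gene, from 49.6 ± 3.7 to 22.5 ± 3.9 CPM (-1.13 ± 0.17, adjusted p = 0.0478). Crybb1, a lens crystallin gene, fell from 302 ± 54 to 147 ± 33 CPM (-1.03 ± 0.16), and Ccl21a (ENSMUSG00000094686), a chemokine gene with near-identical copies among which reads can be split, from 50.3 ± 12 to 19.7 ± 1.8 CPM (-1.36 ± 0.19), both at adjusted p = 0.0478. Markers of cartilage and bone were lower in these spots in 12 of 12 cases (median -0.4) and those of muscle in 10 of 10 (median -0.35), but those of the eye in 6 of 10 (median -0.12). Next among the higher genes, without passing, were Lhx6 (1.74 ± 0.31, adjusted p = 0.168) and Gli1, a target of hedgehog signalling (0.75 ± 0.14, adjusted p = 0.209). The count was 53 without Control 1, 71 without Control 2, 89 without Foxc1 mutant 1 and 121 without Foxc1 mutant 2. DESeq2 called 2 genes, and RLE normalization, finer clusters, thinning and the stricter UMI minimum called none (edgeR, 660 at an unadjusted p under 0.05 in the unaltered comparison). Those 660 of 12840 genes were near the share expected with no true change.

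Of the 21 lists, 3 were called in the mesenchyme by camera. Mitochondrial transcripts were lower in 13 of 13 cases (median -0.57, adjusted p = 9.38e-18), erythroid genes higher in 9 of 9 (median 0.29, adjusted p = 0.00104) and Notch targets higher in 6 of 6 (median 0.26, adjusted p = 0.0348). With an estimated correlation each of these lists had an adjusted p of 0.722. The other lists had adjusted p between 0.0835 and 0.874. Meningeal fibroblast genes were lower in 13 of 17 cases (median -0.2, adjusted p = 0.0835), with Col1a1, Foxd1 and Slc6a13 lower and Foxc1, Foxc2 and S100a6 higher when adjusted over the list alone. Genes of retinoic acid synthesis and transport split evenly, 5 higher and 5 lower (median -0.01, mean 0). The meningeal cluster made up only 22.6% and 19.1% of mesenchyme spots in Control 1 and 2, and 26.4% and 28.7% in Foxc1 mutant 1 and 2. In that cluster 3 genes of this list were higher and 4 lower (median -0.37, camera adjusted p = 0.373). Adjusted over the list alone, 4 passed there, 2 higher and 2 lower. In the mesenchyme as a whole, median and mean, or median and test, differed in sign for retinoic acid synthesis and transport, cell cycle, endothelium, Cajal-Retzius cells and stress genes. The Notch target call was lost without Control 2 (adjusted p = 0.341), without Foxc1 mutant 2 (0.509), over interior spots (0.212), with marker scores (0.418) and in the meningeal cluster alone (0.083). The erythroid call was lost without Control 2 (median -0.05, adjusted p = 0.908), over interior spots (0.991) and with marker scores (0.631), and without Foxc1 mutant 1 there were 8 list calls. Pan-neuronal genes were called down without Foxc1 mutant 1 (median -0.23, adjusted p = 0.000853) and up without Foxc1 mutant 2 (0.2, 1.97e-05).

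No gene passed in the ventral telencephalon (0 of 12395 by edgeR, with 863 at an unadjusted p under 0.05 and 51 called by DESeq2). Among the higher genes with the smallest p-values were Gbx1 (0.253 ± 0.36 CPM in Control and 33.2 ± 13 in the libraries labelled mutant, with 0 and 1 UMIs in the Control libraries, adjusted p = 0.0805), Rxrg (2.59 ± 0.36), Six3os1 (1.93 ± 0.29) and Six3 (1.61 ± 0.26), the last 3 at adjusted p = 0.101. Gbx1, Rxrg and Six3 encode transcription factors. Among lower genes these were the bone gene Ibsp (-1.84 ± 0.23, adjusted p = 0.0936), and Gabra2, Col1a1, Cryga and Cldn5 (log2 fold changes -1.43, -1.75, -1.8 and -1.35, adjusted p = 0.101). The sections did not share their ventral clusters, as described above, and the markers of this region itself were higher in 13 of 14 cases (median 0.73). Camera called 12 of the 21 lists, 3 up and 9 down, and none with an estimated correlation (smallest adjusted p = 0.414). Called up were hypoxia and glycolysis (15 of 16 higher, median 0.721), cell cycle (26 of 28, 0.451) and erythroid genes (8 of 8, 0.569). Lists called down included meningeal fibroblasts (16 of 17 lower, -1.025), Cajal-Retzius cells (7 of 8, -1.239) and retinoic acid synthesis and transport (5 of 8, -0.749). Each of these directions was that of the cortex. Calls numbered 87 without Control 1, 61 without Control 2, 328 without Foxc1 mutant 1 and 126 without Foxc1 mutant 2.

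No gene passed over whole sections either (0 of 15729 by edgeR, with 882 at an unadjusted p under 0.05 and 56 called by DESeq2). Among the higher genes with the smallest p-values were Gbx1, the homeobox gene Hoxc5 and the neuropeptide gene Tac1 (adjusted p between 0.102 and 0.294). Among lower genes the smallest p-values belonged to the collagenase gene Mmp13 (9.78 ± 2.95 CPM in Control and 0.521 ± 0.17 in the libraries labelled mutant, adjusted p = 0.102), the keratin genes Krt79, Krt17 and Krt15, and Kera, which encodes a proteoglycan of the cornea (adjusted p between 0.102 and 0.183). Camera called 11 of the 21 lists, 4 up and 7 down, and none with an estimated correlation (smallest adjusted p = 0.704). Erythroid genes were higher in 9 of 9 cases (median 1.05). There were 78 calls without Control 2 and 13 without Foxc1 mutant 1, and none without Control 1 or without Foxc1 mutant 2.

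Whether the mutant effect differed between cortex and ventral telencephalon was tested directly, and no gene of 12709 passed (edgeR interaction, 689 at an unadjusted p under 0.05). Those 689 genes were near the share expected with no true change. DESeq2 was not run on this test. The smallest adjusted p was 0.0557, for Foxp1, a transcription factor gene of striatal and cortical neurons, with a log2 fold change of -0.69 in the cortex and 1.08 in the ventral telencephalon. Without single libraries the count was 19 (Control 1), 83 (Control 2), 108 (Foxc1 mutant 1) and 0 (Foxc1 mutant 2), and marker scores gave 89.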

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

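All tests of explanations in this part were chosen after the results they weigh had been seen. No group holds the 4 sections that a test for outlying samples needs.

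The cluster led by haemoglobin genes, which no comparison took as a region though whole sections include it, covered 3.121% of spots in Foxc1 mutant 1 (67 of 2147) and 3.879% in Foxc1 mutant 2 (59 of 1521). These shares stood out because they lay above those of the Control sections, with 13 of 1318 spots (0.986%) in Control 1 and 0 of 1614 in Control 2, which allows a share of up to 0.186% by this cluster label (3 counts, counting error only). The assignment itself moved far beyond that: by marker score blood covered 11.08% in Control 1, 3.346% in Control 2 (54 of 1614), 13.74% in Foxc1 mutant 1 and 16.63% in Foxc1 mutant 2.

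Foxc1 counts were higher in the libraries labelled mutant. Transcript from a part of the gene that the deletion leaves in place is a candidate explanation: the Foxc1 level of the libraries labelled mutant was 2.651 times the Control level in the meningeal cluster, where a deletion covering the counted part would leave almost none. This value restates the pattern and is no separate support. Retained transcript would account for its presence, not for a level above Control. An exchange of all 4 labels would need retained transcript as well, since the libraries labelled Control held 409 and 222 CPM in the meningeal cluster. Whether the labels were exchanged cannot be told from these values. The share of cortex spots near the meningeal cluster differed by -13.96 percentage points (libraries labelled mutant minus Control), but which genotype should have the lower share is not known from the labels. An effect of the mutation on transcript levels stays open and was not tested.

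Fibroblast genes lower in the cortex of the libraries labelled mutant may in part reflect less free RNA from tissue outside the brain. Markers of cartilage and bone, muscle and the eye had a pooled median log2 fold change of -1.752 in cortex spots (27 of 27 lower), but surface epithelium, outside this pool, was lower in 7 of 9 cases (-0.686) and blood higher in 7 of 7 (0.518), so tissues outside the brain did not all move alike. Over interior spots the list median was -1.49 (SE over list members 0.327, which leaves out the spread between sections). This argues against spots that adjoin another region as the whole cause. Spots at the tissue edge could stay in this set, so their part was not weighed. A different spread of the called transcripts within sections cannot be told apart from lower totals: over whole sections the genes called lower had a median of -0.454, with Slc22a6 at -2.43 and Islr at 0.02. The meningeal fibroblast list was also lower in the ventral telencephalon (16 of 17 genes, median -1.025), so its shift was not limited to the cortex. A loss of meningeal cells over the cortex in the mutant stays open.

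Hypoxia and glycolysis genes were higher in the cortex of the libraries labelled mutant. Without Control 1 the list median was still 0.537 (SE over list members 0.102, which leaves out the spread between sections). This argues against the RNA quality of that library as the sole cause, but it rests on 1 Control section. A larger share of ventricular zone cannot be told apart. Within the ventricular cluster the median was 0.579, but pan-neuronal genes (13 of 16) and genes of excitatory neurons (12 of 13) were lower there too. The makeup of that cluster may thus differ between the labels as well. Developmental stage cannot be told apart either: the list level and the embryonic share of beta globin had a rank correlation of 0.2 over 4 sections, too few for a test. The list was also higher in the ventral telencephalon (15 of 16 genes, median 0.721), so its shift was not limited to the cortex. An effect of the mutation stays open and was not tested.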

How the results depend on the processing

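Most counts moved with the setting. The alternatives without the mixed cluster, with haemoglobin, mitochondrial and ribosomal protein genes left out, with crossed numbers, and those of single clusters were chosen after seeing the data. The cause of each move was not tested. A left-out section leaves 1 section in its group, which is assumed to vary like those of the other group.

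DESeq2 called 65 genes in the cortex, 2 in the mesenchyme, 51 in the ventral telencephalon, 56 in the whole section, 0 in the meningeal cluster (430 at an unadjusted p under 0.05 by edgeR) and 36 in the ventricular cluster. RLE normalization gave 9 in the cortex, 0 in the mesenchyme and 1 for the interaction of cortex and ventral telencephalon. Without a filter on low counts there were 350 in the cortex, 112 in the mesenchyme, 291 in the ventral telencephalon, 152 in the whole section, 53 in the meningeal cluster and 85 for the interaction. Libraries thinned to the smallest gave 0 in the cortex, 0 in the mesenchyme, 3 in the ventral telencephalon and 0 in the meningeal cluster (edgeR; DESeq2 counts above). Leaving out haemoglobin, mitochondrial and ribosomal protein genes gave 23 in the cortex and 51 in the ventricular cluster. Clusters at resolution 2.0 gave 0 in the cortex, 0 in the mesenchyme and 3 in the ventral telencephalon. Interior spots gave 0 in the cortex and 8 in the mesenchyme, of which 2 were shared with the 5, and the cortex without the mixed cluster gave 0. At least 1000 UMIs per spot gave 0 in the mesenchyme, and marker scores 15 there, with 1 shared, and 89 for the interaction.

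With the replicate number as a block the counts were 278 in the cortex, 13 in the mesenchyme, 122 in the ventral telencephalon, 10 in the whole section, 13 in the meningeal cluster and 0 in the ventricular cluster. Deviations of same-numbered sections correlated at -0.069 in the cortex, -0.193 in the mesenchyme, -0.335 in the ventral telencephalon, -0.199 in the whole section, -0.184 in the meningeal cluster and -0.071 in the ventricular cluster, so the sections share only a number. Crossed numbers as a block gave 145 in the mesenchyme, 334 in the ventral telencephalon, 118 in the whole section and 78 in the meningeal cluster.

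Leaving out 1 section gave 68 to 1964 genes in the cortex, 53 to 121 in the mesenchyme, 61 to 328 in the ventral telencephalon, 0 to 78 in the whole section, 2 to 73 in the meningeal cluster, 52 to 254 in the ventricular cluster and 0 to 108 for the interaction. It gave 9 to 18 lists in the cortex and 2 to 8 in the mesenchyme. A correlation estimated per list left 0 lists in the cortex (smallest adjusted p = 0.236) and 0 in the mesenchyme (0.722), and fry left 4 and 0. Interior spots left 1 list in the mesenchyme. With the replicate number as a block, Notch receptors, ligands and modulators in the cortex lost their call (0.0651).

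The Control share of spots was 14.65% (marker score) and 15.24% (resolution 2.0) for the cortex, 8.04% and 9.358% for the ventral telencephalon, and 15.74% and 19.72% for the mesenchyme. The mutant share of the mesenchyme was 10.43% with marker scores and 14.94% at resolution 2.0. Leaving out 1 section gave shares of 20.51% to 21.17% (Control) and 10.45% to 14.9% (mutant) for the cortex, 3.945% to 5.948% and 12.86% to 19.2% for the ventral telencephalon, and 16.54% to 18.44% and 14.2% to 14.81% for the mesenchyme.

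Log2 fold changes of some named genes turned sign, none of them called in the unaltered fit or where the sign turned. Of these genes, Sox2 (0.682 without Control 1, adjusted p = 0.0132), Tbr1 (0.927 without Control 2, 1.27e-05) and Mapt (0.872 without Foxc1 mutant 2, 0.000117) were called in other fits, as were Lhx6, Hbb-bt and Vtn. With 1 section left out, the cortex values ran from -0.284 to 0.682 for Sox2, -0.129 to 0.552 for Hes1, -0.082 to 0.435 for Notch1, -0.356 to 0.927 for Tbr1, -0.307 to 0.318 for Neurod6 and -0.782 to 0.009 for Cyp26b1. Signs turned without Control 1 (Tbr1, Cyp26b1), Control 2 (Sox2, Hes1, Notch1, Neurod6), Foxc1 mutant 1 (Neurod6, 0.018) and Foxc1 mutant 2 (Hes1, -0.067). Resolution 2.0 gave Sox2 -0.110 and Notch1 -0.107, marker scores Sox2 -0.137 and Notch1 -0.149, interior spots Tbr1 -0.057, and the cortex without the mixed cluster Sox2 -0.110, Tbr1 -0.125 and Cyp26b1 0.050. In the mesenchyme the values ran from -0.408 to 0.067 for Smad6 (turned without Control 1), -0.833 to 0.044 for Cntn2 (without Control 2), and -0.074 to 0.534 for Numbl, -0.016 to 0.872 for Mapt and -0.025 to 0.393 for C1qc (without Foxc1 mutant 1). Resolution 2.0 gave Neurod1 0.162 and Tyrobp -0.101, marker scores Lhx6 -0.184 and C1qc -0.039, and interior spots Rdh10 0.214, Snap25 -0.161, Vtn 0.173, Id1 -0.036 and Hbb-bt -0.047.

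The test direction of some lists turned. Values are medians, and a median can differ in sign from the test. In the cortex this held for radial glia with marker scores (-0.142) and without Control 2 (-0.162, in a range up to 0.398 with 1 section left out), pan-neuronal genes without Foxc1 mutant 2 (-0.082, range from -0.419), Wnt targets over interior spots (0.289), with marker scores (0.116), without the mixed cluster (0.161) and without Control 2 or Foxc1 mutant 1 (range -0.669 to 0.355), and excitatory neurons with the replicate number as a block (0.115) and without each section but Control 1 (range -0.236 to 0.397). In the mesenchyme, interior spots gave meningeal fibroblasts -0.138, basement membrane 0.099, endothelium 0.225, Cajal-Retzius cells 0.314, Wnt targets 0.041, BMP targets -0.070 and macrophages -0.150. Marker scores gave retinoic acid synthesis -0.137, Notch receptors -0.064, pan-neuronal genes -0.143, basement membrane -0.026, BMP targets -0.120, macrophages -0.095 and stress genes -0.021. The meningeal cluster alone gave retinoic acid synthesis -0.370, intermediate progenitors 0.062, pan-neuronal genes -0.161 and cell cycle 0.080. With 1 section left out, the mesenchyme medians ran from -0.155 to 0.058 for retinoic acid synthesis and -0.054 to 0.732 for erythroid genes (turned without Control 2), -0.256 to 0.291 for excitatory neurons and -0.195 to 0.168 for endothelium (Control 2, Foxc1 mutant 2), -0.230 to 0.203 for pan-neuronal genes (Control 1, Foxc1 mutant 1) and -0.035 to 0.043 for stress genes (Control 1). They ran from -0.173 to 0.080 for intermediate progenitors, -0.107 to 0.028 for basement membrane, -0.328 to 0.006 for Cajal-Retzius cells, -0.001 to 0.328 for hypoxia and glycolysis and -0.110 to 0.117 for BMP targets (Foxc1 mutant 2). Of the lists that turned, excitatory neurons in the cortex without Control 2 (adjusted p = 0.00364) and pan-neuronal genes in the mesenchyme without Foxc1 mutant 1 (0.000853) were called in the turned direction. Of the named genes, 10 lost their call under RLE normalization and 143 kept their direction and side of the threshold. Interior spots of the ventral telencephalon, and the interaction over interior spots, were not run, because Control 1 had 4 such spots, under the minimum of 10.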

Other observations

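The comparisons of single clusters in this part were chosen after the data had been seen, and their directions rest on labels that the Foxc1 counts could not check.

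In the ventricular cluster, led by Fabp7, Lhx2 and Neurog2, 98 of 9394 genes passed the threshold, 30 higher and 68 lower in the libraries labelled mutant (edgeR). Nr2f1, a nuclear receptor gene that patterns the cortex, rose from 42.3 ± 1.4 to 189 ± 39 CPM (SD, n = 2 each; log2 fold change 2.17 ± 0.24 SE, adjusted p = 0.000149). The radial glia receptor gene Fgfr3 rose by 1.47 ± 0.33 on the log2 scale (adjusted p = 0.0375), the metallothionein gene Mt1 by 1.46 ± 0.24 (0.00609), AW047730 by 1.4 ± 0.24 (0.00922) and the replication gene Fen1 by 1.26 ± 0.27 (0.0323). Foxc1 rose from 54 ± 37 to 188 ± 59 CPM (2.03 ± 0.33, adjusted p = 0.00563) and was not called by DESeq2 (adjusted p = 0.308). Among the lower genes were Cldn11 (28.1 ± 9.1 to 0.975 ± 1.4 CPM, adjusted p = 0.00446), the lens crystallin genes Crygb (adjusted p = 0.0122) and Crybb3 (0.000442), the muscle actin gene Actc1 (0.033) and Kif20b, a kinesin gene of dividing progenitors (0.0145). Camera called 10 of 20 lists. Radial glia genes were not among these (10 of 18 higher, median 0.02, adjusted p = 0.888), with 3 members higher and 2 lower when adjusted over the list alone. Intermediate progenitors (7 of 10 higher, median 0.43, adjusted p = 0.00921), Notch targets (4 of 4 higher, 0.44, 0.0295) and cell cycle (18 of 28 higher, 0.32, 0.00235) were called up, with adjusted p between 0.528 and 0.609 with an estimated correlation. Pan-neuronal genes (13 of 16 lower, -0.42, 9.12e-05), excitatory neurons (12 of 13 lower, -0.41, 4.2e-05) and mitochondrial transcripts (13 of 13 lower, -0.89, 5.45e-22) were called down, each at adjusted p = 0.528 with an estimated correlation. The other called lists were hypoxia and glycolysis (14 of 14 higher, 0.58, 6.12e-09), erythroid genes (7 of 7 higher, 0.61, 0.00258), meningeal fibroblasts (8 of 9 lower, -0.63, 0.00258) and mural cells (5 of 5 lower, -0.94, 0.0381), with adjusted p between 0.528 and 0.53 with an estimated correlation. Markers of cartilage and bone, muscle and the eye were lower in 10 of 10 cases (median -1.3) in the same spots. No gene passed with the replicate number as a block. DESeq2 called 36 genes, and the gene count was 51 with haemoglobin, mitochondrial and ribosomal protein genes left out, 254 without Control 2 and 52 without Foxc1 mutant 2. The summed library of Control 1 held 338815 UMIs against 1023554 in Foxc1 mutant 2, and the self-test recovered 39% of 2-fold changes.

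In the meningeal cluster camera called 4 of 21 lists, each at adjusted p = 0.725 with an estimated correlation. Erythroid genes were called up (7 of 7 higher, median 0.69, 9.59e-08). Cajal-Retzius cells (5 of 7 lower, -0.59, 0.000596), mitochondrial transcripts (12 of 12, -0.3, 0.00398) and excitatory neurons (5 of 10, -0.25, 0.0392) were called down. In the same cluster 5 of 9819 genes passed (edgeR), and DESeq2 called none. By edgeR 430 genes had an unadjusted p under 0.05, fewer than expected with no true change. Besides Foxc1, the smooth muscle actin gene Acta2 rose from 86.4 ± 19 to 195 ± 2.5 CPM (1.18 ± 0.19, adjusted p = 0.0487). Slc22a6 fell from 96.7 ± 31 to 22.8 ± 0.82 CPM (-2.07 ± 0.29, adjusted p = 0.0386), the amino acid transporter gene Slc38a5 from 36 ± 7 to 5.67 ± 0.69 CPM (-2.65 ± 0.42, adjusted p = 0.0463) and the lens gene Cryga from 181 ± 37 to 65.1 ± 21 CPM (adjusted p = 0.0463). Calls numbered 2 without Control 1, 12 without Control 2, 73 without Foxc1 mutant 1 and 57 without Foxc1 mutant 2.

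Embryonic beta globins made up 13.6% of beta globin UMIs in Control 1, 8.56% in Control 2, 6.71% in Foxc1 mutant 1 and 28.6% in Foxc1 mutant 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 815, 509, 290 and 226 UMIs in Control 1, 792, 835, 388 and 237 in Control 2, 881, 998, 469 and 215 in Foxc1 mutant 1 and 0 each in Foxc1 mutant 2. Xist had 1, 2, 0 and 1 UMIs in the same order of sections. The absence of Y-linked UMIs argues against 1 shared embryo for Foxc1 mutant 2 and the other sections. The 2 libraries labelled mutant thus differed in Y-linked counts and in the embryonic share of beta globin. Whether the other sections came from separate embryos cannot be told from these counts.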
